A study of Mus musculus with 10 samples.

How the data were processed

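Total RNA from the lungs of 4 control and 6 smoke-exposed mice was extracted with Trizol, amplified and labelled as cRNA, and hybridised to 1 Affymetrix Mouse 430 2.0 array per mouse, per the labels' protocols and the series' design text. The authors deposited 1 intensity per probe set and array on a linear scale. The program that summarised the probes and its settings are not given in the sources used here. The mean without the lowest and highest 2% of values was 499.8 to 499.9 on every array, as after scaling to a common target. No detection calls were used, so a dim probe set has no stated background.

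The median log2 intensity ran from 7.01 to 7.70 over the arrays, a wider span than the limit of 0.3 set before the data were examined, so quantile normalization was the main setting. The 1 value of 0 was set to the smallest positive value, log2 was taken, the arrays were quantile normalized and values under the 10th percentile of the table (an intensity of 15.8) were set to it. The design written before the data were examined named the floor ahead of log2; here it followed the normalization, and without any floor 3 genes were higher and 94 lower, as with it. Of 45101 probe sets, 64 Affymetrix controls were left out, and the upper 60% of the others by mean log2 value were tested, 27022 in all. Gene symbols came from the platform annotation, and a symbol table for GRCm38.p6 changed 0 of them. Among 45037 probe sets other than controls, 34945 carried 1 symbol, 932 several and 9160 none here. A gene was represented by its tested probe set with 1 symbol and the highest mean, giving 13381 genes. Other probe sets of a gene can disagree, as for Csf1, Cenpa, Klf6, Egr2, Hsp90aa1 and Gclc, where at least 1 had the opposite sign, or differ in size, as for Tiparp, Mt1, Fkbp5, Hsp90b1, Cyp1b1, Crtc1 and Zbtb16. Among the changed probe sets, 10 had several symbols and 13 had none, and these are not named. No genome was used, so positions are not given.

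Smoke was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), with Benjamini-Hochberg adjustment over tested probe sets and a threshold of 0.05; all tests were two-sided. Of 50 gene lists fixed in advance (24 pathways and 26 sets of cell type markers), 873 of 954 listed genes matched a symbol and 48 lists had the 5 measured members required. They were tested with camera at a preset correlation of 0.01, adjusted over all lists, with an estimated correlation and fry as alternatives. Exposure markers under the filter had an exact permutation test. Named genes were, by a rule fixed in advance, the 12 largest rises and falls past the threshold (where fewer passed, those that did and the next by p up to 6), up to 4 members of each list that passed or held at least 3 changed genes, and 8 exposure markers. The rule left symbols that are only clone or predicted names, such as those that start with Gm or end in Rik, out of the largest rises and falls; Gm4951, at a log2 change of -3.37, was left out in this way. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

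The fit was tested on simulated arrays with the means and spreads of the 27022 real probe sets. Probe sets were drawn independently of each other and with the same spread on every array, unlike the real arrays. Of 50 genes lowered by a log2 change of 2, 76% were recovered, and of 50 raised by 2, 74%. At a change of 1 the shares were 22% for lowered and 30% for raised genes, with 5 false calls in all. In a separate simulation of the 48 lists, drawn in the same way, 1 list lowered by 1 was called and 0 others. With genes drawn independently, it gives no error rate for lists of correlated genes. Other splits of the real arrays called up to 21 lists.

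The lowest and highest correlations between any pair of arrays were 0.747 and 0.975, and 0 pairs held identical values. Alternatives covered normalization, filter, floor, variance model, array weights, replicate number, Xist level, each array left out, choice of probe set, the list test and the rule in the series' design text. That rule names 9 pairwise comparisons, which 4 and 6 arrays do not give, so it was run as 2 of every 3 of the 24 pairs. After seeing the data 4 alternatives were added, for smoke arrays 1 and 2, for these or smoke arrays 5 and 6 left out with an estimated correlation, and for the actin ratio.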

Results

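Lung RNA from 10 C57BL/6J mice aged 2 weeks was measured on Affymetrix Mouse 430 2.0 arrays, 1 array per mouse. The smoke group held 6 mice that had been placed with their mother in a chamber of cigarette smoke from the age of 1 day, for 1 hour a day over 7 days and then 2 hours a day over 7 more days, at an average of 90 mg of particulate matter per cubic metre. The control group held 4 mice kept in filtered air, away from the smoke group. The labels leave sex unknown and give no litter or array batch, so the p-values measure the spread between these arrays. The number of arrays limits the precision of every value. The comparison asked which lung genes differ after 2 weeks of neonatal smoke exposure.

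Genes that respond to tobacco smoke components were examined first, as a check on the labels. Cyp1b1, a cytochrome P450 under control of the aryl hydrocarbon receptor, rose by 2.18 ± 0.39 (log2 change ± SE; limma, adjusted p = 0.0261) and was higher in 6 of 6 smoke arrays than in any control array. Its log2 intensity was 7.53 ± 0.70 (SD, n = 4) in controls and 9.70 ± 0.67 (SD, n = 6) after smoke. Cyp1a1 had a log2 change of 1.52 ± 0.36 and lay above every control in 5 of 6 smoke arrays, but did not pass (adjusted p = 0.129). Nqo1, a quinone reductase, had a log2 change of 0.94 ± 0.21, above every control in 6 of 6 smoke arrays, and did not pass either (adjusted p = 0.101). The values were -0.19 ± 0.15 for Tiparp, 0.30 ± 0.30 for Gclc and 0.20 ± 0.27 for Mt1, with adjusted p-values of 0.697, 0.763 and 0.830. Other probe sets of the same genes differed, at -1.97 and -1.67 for Tiparp, -0.86 for Gclc and 1.63 for Mt1. The other tested probe set of Cyp1b1 had a smaller log2 change, 1.09. Over single omissions Gclc ran from 0.07 without control replicate 2 to 0.47 without smoke replicate 1, and Mt1 from 0.08 to 0.43 without control replicates 3 and 4 in turn. Ahrr, the repressor of the same receptor, lay below the filter on dim probe sets, with intensities of 4.3 to 29.9 in controls and 29.8 to 204.9 after smoke. Its control mean of 15.5 ± 11.6 (SD, n = 4) lay under the floor of 15.8, so its log2 difference of 2.00 is a lower bound (exact two-sided permutation p = 0.00952, where 0.00476 is the smallest p that 4 against 6 arrays allow) and is not counted as a check on the labels. Hmox1, also below the filter and with control intensities from 4.7, had an exact two-sided permutation p of 0.205. The Cyp1b1 call was lost without control replicate 1, 2 or 3 or smoke replicate 3 or 4 (adjusted p up to 0.141), at log2 changes of 1.95 to 2.43 over all single omissions, and without the filter (adjusted p = 0.0830).

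Smoke-exposed lungs held much lower levels of interferon-induced genes than control lungs. Of 13381 genes tested, 94 were lower and 3 higher (limma, adjusted p under 0.05), and 43 of the 94 belonged to the type I or type II interferon lists fixed before the data were examined. All 97 changed by at least 1.5-fold, and the falls ranged from 1.70-fold to 20.7-fold. The largest fall, that of Ifi204, depends in part on the floor, where its value in smoke array 4 lay (log2 of 3.98). Ifit3 also fell 20.7-fold, with no array at the floor. In all 97 genes the smoke and control arrays did not overlap. Over all genes tested 547, or 4.09%, did not overlap, where chance gives 0.952%. Counted by probe set, 3 were higher and 146 lower. At an unadjusted p under 0.05 there were 1367 genes, 769 higher and 598 lower. Smoke arrays 1 and 2 had actin 3' to 5' ratios of 31.6 and 29.4, against 3.96 to 10.4 in controls. Without both, 10 genes were higher and 115 lower, and with the log2 actin ratio as a covariate 151 were higher and 220 lower, both settings being chosen after seeing the data. With array weights, 41 were higher and 142 lower. Without smoke arrays 5 and 6, a setting fixed in advance as the arrays numbered 1 to 4, 418 were higher and 324 lower. The lower share was thus 43.7%, against 96.9% with all arrays. The genes called there included all 94 lower and all 3 higher genes called with all arrays. Smoke arrays 5 and 6 were the only smoke arrays high in Xist, used here as a marker of sex. This setting therefore sets low-Xist smoke arrays against 2 high-Xist and 2 low-Xist controls. Without control replicate 2 or 3 the lower genes numbered 58 and 60, and without control replicate 1, 2 or 3 the changed probe sets fell in number from 149 to 96, 87 and 91.

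In the type I interferon list, 29 of 36 measured members fell, none rose and 7 did not pass, with a median log2 change of -2.10 (camera, adjusted p = 9.84e-76, and adjusted p = 0.000835 with an estimated correlation). Adjusted over the list alone, 33 fell. Ifit1, which binds foreign RNA, and Ifit3 had log2 changes of -4.34 ± 0.24 (adjusted p = 7.20e-06) and -4.37 ± 0.32 (adjusted p = 4.36e-05). Ifit1 had a log2 intensity of 12.74 ± 0.15 (SD, n = 4) in controls and 8.40 ± 0.46 (SD, n = 6) after smoke. Zbp1, a sensor of nucleic acids, fell by 3.78 ± 0.44, and Usp18, the protease that removes ISG15 from proteins, fell by 3.16 ± 0.19. Herc6, the ligase that attaches ISG15 in mice, fell by 3.07 ± 0.29. All of these genes were lower in 6 of 6 smoke arrays than in any control.

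In the type II interferon list, 14 of 25 measured members fell, none rose and 11 did not pass, with a median of -1.74 (camera, adjusted p = 2.33e-36, and adjusted p = 0.0125 with an estimated correlation). The latter was 0.0867 without smoke arrays 5 and 6. Adjusted over the list alone, 20 fell. The immunity-related GTPases Iigp1 and Ifi47 fell, with log2 changes of -3.37 ± 0.21 and -2.83 ± 0.21, as did the guanylate-binding proteins Gbp3 and Gbp6, at -3.08 ± 0.23 and -3.02 ± 0.27. Outside both lists, genes that fell included Ifi204 at -4.37 ± 0.60, Slfn4 at -4.26 ± 0.37, Zbtb16 at -3.74 ± 0.71 and Ms4a4c at -3.002 ± 0.231 (adjusted p = 0.00399, 0.000105, 0.0406 and 4.84e-05).

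**Figure D1:**
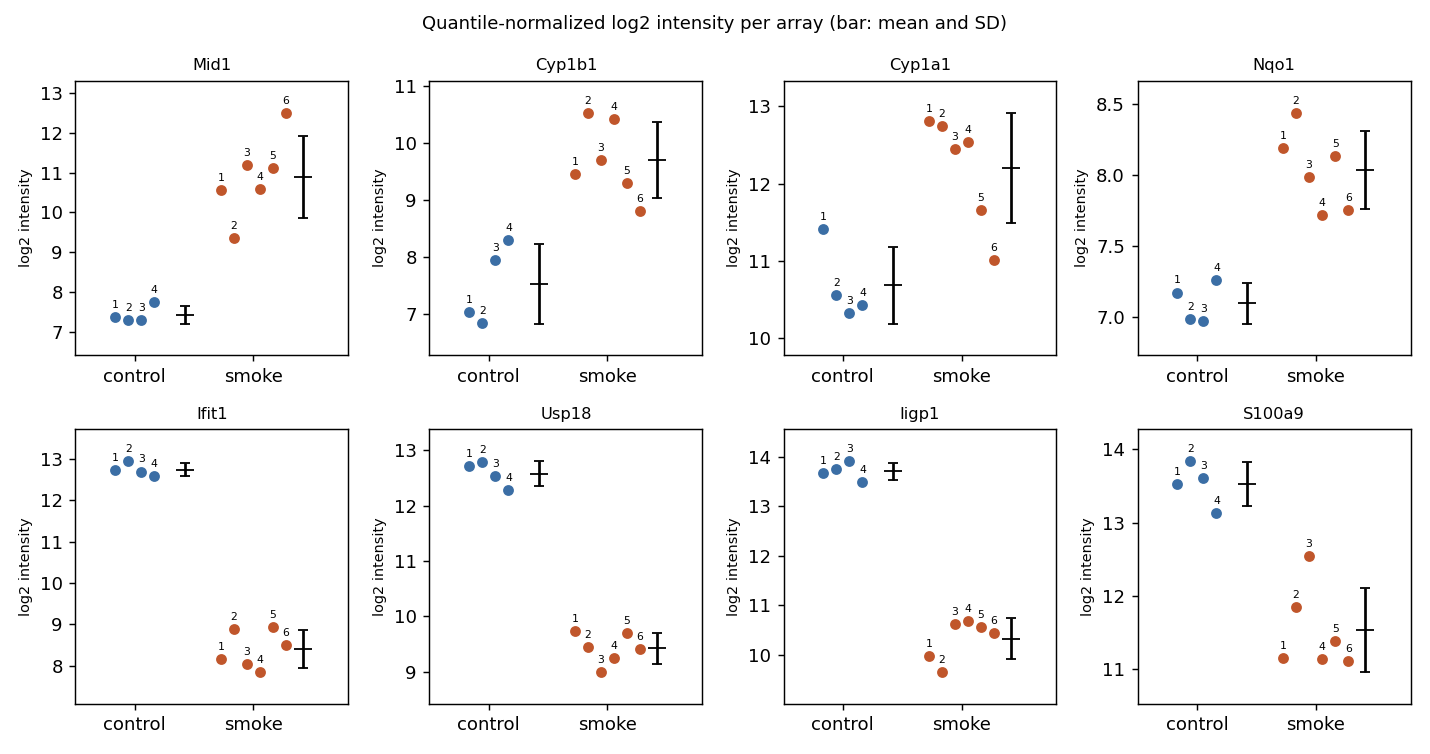
Quantile-normalized log2 intensity (vertical axis) of 8 genes on each array (points, numbered by replicate), with the group mean and SD (black bars) for 4 control and 6 smoke arrays. Ifit1 averaged 12.74 in controls and 8.40 after smoke with no overlap, while the Cyp1a1 values of smoke array 6 lay within the control range.

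In the MHC class I list, 4 of 14 measured members fell and 10 did not pass, with a median of -0.92 (camera, adjusted p = 3.07e-16, and adjusted p = 0.0138 with an estimated correlation). Adjusted over the list alone, 10 fell. The 4 were Nlrc5, a transactivator of MHC class I genes, at -2.78 ± 0.26, the immunoproteasome subunit Psmb8 at -2.03 ± 0.39, the peptide transporter subunit Tap1 at -1.65 ± 0.23 and its partner Tapbp at -0.89 ± 0.16. All 4 also belong to the type II interferon list and are counted among its members that fell, so they are not a separate result. Psmb8 lost its call in 7 of the 10 single omissions, without the filter and without a variance trend (adjusted p = 0.117 and 0.0617). Tapbp lost it in 4 single omissions, with median centring and without a variance trend (adjusted p = 0.0589 and 0.0638). With an estimated correlation the list's adjusted p was 0.0817 without smoke arrays 1 and 2, and 0.0732 without smoke arrays 5 and 6.

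Neutrophil markers were lower as well. Of 10 measured members 4 fell and 6 did not pass, both over all genes and adjusted over the list alone, with a median of -0.80 (camera, adjusted p = 2.20e-07, and adjusted p = 0.0125 with an estimated correlation). The calcium-binding proteins S100a9 and S100a8 fell, with log2 changes of -1.995 ± 0.277 and -1.60 ± 0.24, as did Stfa2l1 at -1.99 ± 0.39 and the collagenase Mmp8 at -1.39 ± 0.22 (adjusted p = 0.00423, 0.00777, 0.0469 and 0.0128). The S100a8 call ended when the values were used as deposited (adjusted p = 0.0597) or centred on the median (adjusted p = 0.0841), and the Stfa2l1 call ended in 8 of the 10 single omissions. The list's median was -0.53 without control replicate 4, -0.47 without the filter and -1.40 without smoke arrays 5 and 6, where the adjusted p was 0.123 with an estimated correlation. Without control replicate 2 the S100a8 call was lost (adjusted p up to 0.0519), and without control replicate 1, 2 or 3 the Mmp8 call was lost (adjusted p up to 0.0802).

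The 3 higher genes were Mid1, Cyp1b1 and Prss35. Mid1, a microtubule-associated ubiquitin ligase, rose by 3.46 ± 0.46 (adjusted p = 0.00320), from a log2 intensity of 7.42 ± 0.22 (SD, n = 4) to 10.89 ± 1.03 (SD, n = 6), and passed in each single omission. Prss35, a serine protease family member, rose by 1.73 ± 0.32 (adjusted p = 0.0324) and lost its call in 8 of the 10 single omissions, without the filter and without smoke arrays 1 and 2 (adjusted p = 0.0838 and 0.0613). Without control replicate 2, smoke replicate 3 or smoke replicate 4, 1 gene was higher, and without smoke replicate 5 or 6 the number was 6. The next genes by p did not pass: Crtc1 at 1.48 ± 0.29, Lhfpl2 at 1.61 ± 0.32 and Med8 at 0.99 ± 0.20 (adjusted p = 0.0531, 0.0570 and 0.0607). The other tested probe set of Crtc1 was at 0.02.

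Over 48 lists tested, 15 passed with camera's preset correlation, 12 lower and 3 higher. With an estimated correlation 5 held, namely both interferon lists, MHC class I, neutrophil and B cell, and without smoke arrays 1 and 2 this number was 3, namely both interferon lists and neutrophil. Without smoke arrays 5 and 6 it was 1, the type I interferon list (adjusted p = 0.0168). The MHC class I list shares all of its members that fell with the type II interferon list. The B cell list was higher, with a median of 0.57 over 14 members (adjusted p = 0.00123, and adjusted p = 0.0427 with an estimated correlation), although no member passed alone, over all genes or adjusted over the list alone. The call was lost in the upper 40% of probe sets by mean level (adjusted p = 0.0517). Without smoke arrays 1 and 2 the median was 0.37, with an adjusted p of 0.0886 at an estimated correlation, which was 0.319 without smoke arrays 5 and 6. Its members with the smallest p were Blk at 0.80 ± 0.26, Cd79a at 0.98 ± 0.33, Bank1 at 0.61 ± 0.23 and Fcer2a at 1.13 ± 0.43, the last at 0.69 without control replicate 1. The list of xenobiotic response genes was higher with 1 of 8 members past the threshold, Cyp1b1, and 3 adjusted over the list alone, with a median of 0.52 (adjusted p = 0.0111, and adjusted p = 0.232 with an estimated correlation), and lost the call without _x_at and _s_at probe sets (adjusted p = 0.0842). Cyp2s1, another member, was at 0.51 ± 0.22 (adjusted p = 0.486). The G2 and M phase list was higher with none of 28 members past the threshold and 1 adjusted over the list alone, with a median of 0.46 (adjusted p = 6.89e-06, and adjusted p = 0.161 with an estimated correlation). Its examples were Prc1 at 0.93 ± 0.23, Mki67 at 0.94 ± 0.28, Cenpf at 0.70 ± 0.22 and Cenpa at 0.58 ± 0.19.

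The glucocorticoid response list was lower with 1 of 20 members past the threshold, Zbtb16, and 3 adjusted over the list alone, with a median of -0.70 (adjusted p = 2.88e-08, and adjusted p = 0.2497 with an estimated correlation). Without smoke arrays 1 and 2, those with the high actin ratios, the median was -0.30 (adjusted p = 0.000249) and no member passed. The median was -0.33 with array weights and -1.13, with 9 members lower, without smoke arrays 5 and 6. Zbtb16, a zinc finger transcription factor, lost its call in 8 of the 10 single omissions and without the filter (adjusted p = 0.127). Its other tested probe sets were at -2.71 and -1.52. Fkbp5, Pdk4 and Cdkn1a were at -2.14 ± 0.56, -1.45 ± 0.40 and -1.45 ± 0.50 and did not pass (adjusted p = 0.187, 0.219 and 0.370). The list's mean log2 intensity was 11.83 ± 0.20 (SD, n = 4) in controls and 10.97 ± 0.75 (SD, n = 6) after smoke, where it ran from 9.96 to 11.85.

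The remaining 7 lists that passed were lower and lost the call with an estimated correlation. Inflammatory cytokines and chemokines had 1 of 22 members lower, Ccl12, at -2.95 ± 0.50, and 4 adjusted over the list alone, with a median of -0.48 (adjusted p = 5.57e-05, and adjusted p = 0.181 with an estimated correlation). The median was -0.31 without control replicate 4 and -0.12 without the filter. Ccl12 lost its call in 5 of the 10 single omissions and without the filter (adjusted p = 0.0677). Csf1, Ccl6 and Il18 were at -0.92 ± 0.18, -1.26 ± 0.35 and -0.52 ± 0.16. Matrix proteases had 1 of 25 members lower, Mmp8, with 2 lower and 1 higher adjusted over the list alone and a median of -0.29 (adjusted p = 0.0116, and adjusted p = 0.586 with an estimated correlation). The median was -0.16 as deposited, -0.13 with the floor at the 25th percentile and -0.13 without smoke replicate 1. The call was lost with array weights and without smoke arrays 1 and 2, at medians of -0.03 in both (adjusted p = 0.337 and 0.490). Ctss, Timp4 and Adamts1 were at -0.68 ± 0.19, -0.61 ± 0.23 and 0.63 ± 0.18. No member passed in the other lists, and adjusted over the list alone 1 did, in the p53 list. Macrophage and monocyte markers had a median of -0.40 (adjusted p = 0.000918, and adjusted p = 0.306 with an estimated correlation), with Chil3, Mrc1 and Mpeg1 at -0.40 ± 0.17, -0.67 ± 0.30 and -0.62 ± 0.29. Heat shock genes had a median of -0.19 (adjusted p = 0.00291, and adjusted p = 0.161 with an estimated correlation), with Hspa1b, Hsp90aa1, Hsp90b1 and Calr at -0.85 ± 0.27, -0.29 ± 0.10, -0.41 ± 0.15 and -0.50 ± 0.19. The heat shock median was -0.12 without smoke replicate 1 and -0.11 with array weights. Innate defence and complement genes had a median of -0.20 (adjusted p = 0.00616, and adjusted p = 0.492 with an estimated correlation), with Cfb, C2, C1qc and Tlr2 at -1.44 ± 0.54, -0.46 ± 0.22, -0.63 ± 0.33 and -0.42 ± 0.23. The innate defence median was -0.31 without control replicate 2 or without smoke arrays 1 and 2, and -0.40 without smoke arrays 5 and 6, and the call was lost with array weights (adjusted p = 0.0520). p53 targets had a median of -0.32 (adjusted p = 0.0264, and adjusted p = 0.157 with an estimated correlation), and lost the call without smoke arrays 1 and 2 (median -0.08, adjusted p = 0.0986) and with array weights (median -0.06, adjusted p = 0.121). Without smoke replicate 1 the p53 median was -0.17, and the call was lost without the filter and without _x_at and _s_at probe sets (adjusted p = 0.0551 and 0.0558). Trp53inp1, Sesn1 and Plk2 were at -0.71 ± 0.17, -0.56 ± 0.20 and 0.74 ± 0.23. Immediate early genes had a median of -0.08 (adjusted p = 0.0472, and adjusted p = 0.232 with an estimated correlation), with Ccn2, Nr4a3, Klf6 and Egr2 at -0.50 ± 0.13, -1.65 ± 0.60, -0.45 ± 0.21 and -0.60 ± 0.30, and lost the call in 6 of the 10 single omissions. The immediate early median was -0.13 without smoke replicate 2 and -0.24 without smoke arrays 1 and 2, and the call was also lost in the upper 40% by mean level and without smoke arrays 5 and 6 (adjusted p = 0.119 and 0.372). The matrix protease, innate defence and p53 lists each lost the call in 1 single omission, without smoke replicate 1, control replicate 3 and control replicate 1 in turn (adjusted p = 0.135, 0.0604 and 0.0707).

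**Figure D2:**
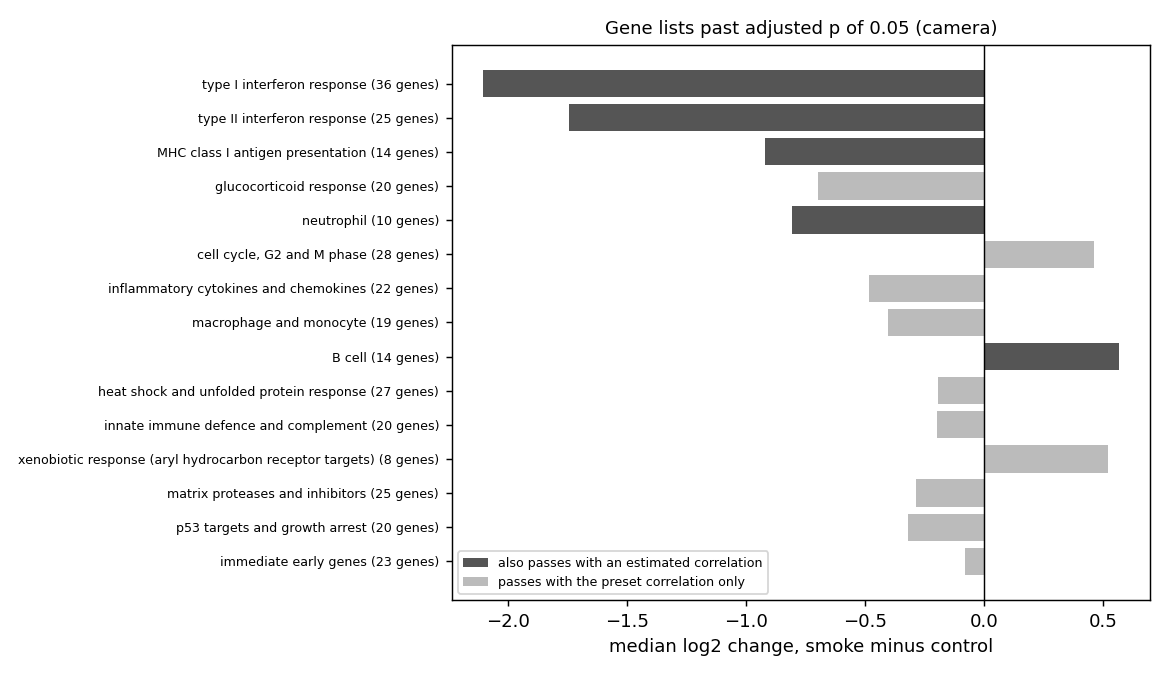
Median log2 change, smoke minus control (horizontal axis), of the 15 gene lists past an adjusted p of 0.05 with camera's preset correlation; dark bars also pass with an estimated correlation. Both interferon lists lie farthest from 0, at -2.10 and -1.74.

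The other 33 lists did not pass (adjusted p of 0.0666 to 0.981), with medians of -0.60 to 0.35. Elastic fibre and alveolar septation genes had a median of 0.26 over 30 members (adjusted p = 0.279), and passed without smoke arrays 1 and 2 (median 0.32, adjusted p = 0.0250) or without smoke replicate 1 (adjusted p = 0.0359), while the median was 0.15 without control replicate 3 (adjusted p = 0.627). With an estimated correlation in camera, the list's adjusted p was 0.693 with all arrays and 0.368 without smoke arrays 1 and 2. DNA replication genes had a median of 0.23 over 28 members (adjusted p = 0.0718), and passed without control replicate 3, smoke replicate 5 or smoke replicate 6 (adjusted p = 0.0363, 0.0166 and 0.0289) or without smoke arrays 5 and 6 together (median 0.47, adjusted p = 0.00566). With an estimated correlation in camera, not run for single omissions, the adjusted p was 0.693 with all arrays and 0.406 without smoke arrays 5 and 6. The DNA replication median was 0.13 without smoke replicate 2 (adjusted p = 0.185), 0.10 without smoke arrays 1 and 2 (adjusted p = 0.455) and 0.10 with array weights (adjusted p = 0.478). Antioxidant genes had a median of 0.13 over 28 members (adjusted p = 0.355), and 0.08 without smoke replicate 2 (adjusted p = 0.330). Markers of alveolar type 2, alveolar type 1 and endothelial cells had medians of 0.05, -0.06 and -0.15 (adjusted p = 0.937, 0.323 and 0.320), and those of T cells had a median of -0.08 (adjusted p = 0.981), with no member past the threshold in these 4 lists. The T cell list's mean was 0.005, and its test pointed to higher values, against the sign of its median. Without smoke arrays 1 and 2 the alveolar type 2 list passed, at a median of 0.29 (adjusted p = 0.0262), and the medians for alveolar type 1, endothelial and T cells were 0.11, 0.08 and 0.10. Without smoke arrays 5 and 6 the endothelial and alveolar type 1 lists passed as lower, at -0.42 and -0.26 (adjusted p = 0.00533 and 0.0221) with 1 member lower in each, and the medians for alveolar type 2 and T cells were -0.24 and 0.12. Over single omissions, in which none of these 4 lists passed, the alveolar type 2 median ran from -0.16 to 0.26, alveolar type 1 from -0.14 to 0.006, endothelial from -0.33 to -0.02 and T cell from -0.18 to 0.12. Of the 33 lists, 7 passed without smoke arrays 1 and 2 (6 higher, 1 lower) and 6 without smoke arrays 5 and 6 (1 higher, 5 lower), and none did so with an estimated correlation (adjusted p of at least 0.293 and 0.406).

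**Figure D3:**
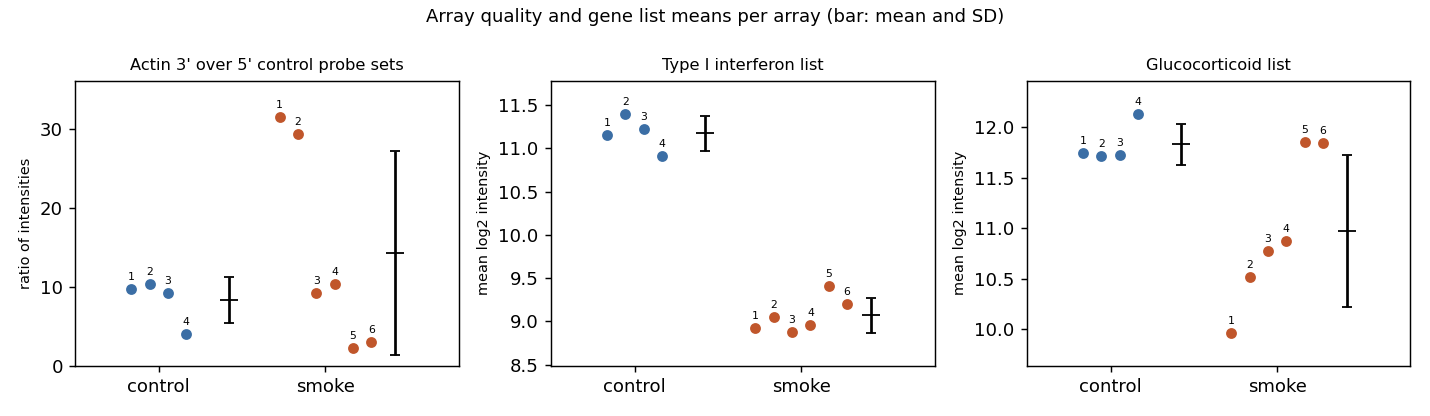
Ratio of the 3' to the 5' actin control probe sets, and mean log2 intensity of the type I interferon and glucocorticoid lists (vertical axes), on each array (points, numbered by replicate), with the group mean and SD (black bars) for 4 control and 6 smoke arrays. The interferon list averaged 11.17 in controls and 9.07 after smoke with no overlap, while the glucocorticoid list ran from 9.96 to 11.85 after smoke.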

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

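The tests of RNA quality, immune cells, sex and shared origin below were chosen after the results were seen; the tests of other splits of the arrays and of the spread among controls were set before. Among 178 groups of values examined, 6 held an array set apart from the others, fewer than the 5% that chance gives.

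Interferon genes were lower in every smoke array, with type I list means of 8.88 to 9.41 against 10.91 to 11.40 in controls. Loss of RNA quality in smoke arrays 1 and 2 does not account for it, since the list's median was -2.10 without them, nor does sex, since it was -2.12 with the Xist level as a covariate. Fewer macrophages, B cells or T cells would lower their markers alike. Yet the lowest median among these lists was -0.40, with an SD of 0.40 over its members. That list joined macrophage and monocyte markers, so a loss of monocytes alone was not tested. The bounds for both immune cell tests were set after the values were known, and under an earlier bound fewer neutrophils stayed undecided. The neutrophil list's median was -0.80 with an SD of 0.76, and lay 1.30 above that of the interferon list. Without smoke arrays 5 and 6 it was -1.40, against -2.01 for the interferon list. That gap of 0.61 was under the SD of 0.71, so the medians do not decide it there. By count, 19 of 36 interferon genes were below the lowest neutrophil marker (21 without smoke arrays 5 and 6). That bound rests on 1 marker, and the genes counted are those that fell furthest, so the count does not decide it. Fewer neutrophils as a part or the whole of the cause therefore stay open. A raised interferon response in all control mice, who were housed apart, cannot be told apart from a lowered response after smoke: the SD of the list mean among controls was 0.998 times that among smoke arrays, which a rise shared by all controls would leave as it is, and a direct effect of smoke (a hypothesis) and unrecorded differences of litter or housing stay open too.

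Glucocorticoid response genes differed among the smoke arrays: the list mean was 11.85 and 11.84 in smoke arrays 5 and 6, near the control mean of 11.83, and 9.96 to 10.87 in the others. The means went in part with the actin ratios, which were lowest in smoke arrays 5 and 6 (2.18 and 2.98) and, among controls, in array 4 (3.96, list mean 12.13), and highest in smoke arrays 1 and 2 (list means 9.96 and 10.51), so RNA quality stays open for these arrays. It does not account for smoke arrays 3 and 4, which at ratios of 9.26 and 10.3, against 9.28 to 10.4 in controls 1 to 3, lay at least 4.76 control SD below the control mean (-4.76 for the nearer one). Smoke arrays 5 and 6 were the smoke arrays with high Xist, but the gap between high-Xist and low-Xist arrays was 0.145 times as large in controls as after smoke, so sex alone is not enough, while a sex-dependent response to smoke was not tested. Deviations of arrays 5 and 6 from the smoke mean correlated at 0.771 across probe sets, which are not independent, consistent with a shared litter, harvest or array batch, although the pair had been noticed first, arrays 1 and 2 weigh on that mean, and shared sex or RNA quality could give the same value.

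Of 100 splits of the 10 arrays into 4 and 6, drawn from 210, 1 (the real one) called as many as 97 genes and the highest other called 3. A random split is therefore unlikely to give that many genes. The splits treat the arrays as exchangeable, so they cannot exclude a litter or batch shared within a group. For probe sets 1 split, the real one, reached 149 and the highest other called 7. For gene lists, 18 of 100 splits called at least 15 lists and the highest other called 21, so chance cannot be excluded for the number of lists.

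Control array 4 stood apart with an actin ratio of 3.96 (9.28 to 10.4 in the other controls), a glucocorticoid list mean of 12.13 (11.72 to 11.74) and a Mid1 log2 value of 7.75 (7.29 to 7.36). Smoke array 1 had a Zbp1 log2 value of 4.37 (6.09 to 6.65 in the other smoke arrays). Smoke array 4 had log2 values of 4.55 for Cfb (6.73 to 7.75) and 12.06 for Tiparp (11.50 to 11.61). Control probe sets, used above only for the actin ratio, exceeded every control array in some smoke arrays and lay below every control array in others. The actin ratio was 31.6 and 29.4 in smoke arrays 1 and 2 (3.96 to 10.4 in controls), and the Gapdh ratio was 9.16 and 5.94 in arrays 2 and 3 (4.82 to 5.89). The Cre spike-in read 30427, 24606 and 14014 in arrays 1, 2 and 4 (9516 to 13416), and the BioB spike-in 674.3 and 600.9 in arrays 1 and 2 (146.3 to 249). In smoke arrays 5 and 6, in that order, all 4 measures lay below every control, with actin ratios of 2.18 and 2.98, Gapdh ratios of 1.40 and 2.13, Cre readings of 6930 and 7475 and BioB readings of 95.3 and 108.3. The Gapdh ratio was also below every control in smoke arrays 1 and 4, at 4.76 and 3.68.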

How the results depend on the processing

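The settings for smoke arrays 1 and 2, alone or with an estimated correlation, for smoke arrays 5 and 6 with an estimated correlation and for the actin ratio were chosen after seeing the data. Of 645 repeats of the 25 named genes that passed, 579 kept the call, 66 lost it and 0 reversed; of 450 repeats of the 15 lists, 380 kept it, 70 lost it and 0 reversed. All 94 lower genes stayed negative under both other scalings, with 89 called as deposited and 87 with median centring.

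Genes higher numbered 3, against 8 as deposited, 6 with median centring, 7 without the filter, 10 in the upper 40%, 5 with the floor at the 25th percentile, 6 with Xist and 14 with the mean of probe sets. Genes higher and lower were 41 and 142 with array weights and 151 and 220 with the actin ratio, and without smoke arrays 1 and 2, 10 were higher. By the rule in the series' design text 265 were higher and 333 lower. That rule was run with an unadjusted p under 0.05 and a fold of at least 1.5. Its counts are therefore not comparable with those at an adjusted p. Probe sets changed were 342, 639 and 241 with array weights, with the actin ratio and without arrays 1 and 2. Lists called were 5 with an estimated correlation, 3 with it and without smoke arrays 1 and 2, 1 with it and without smoke arrays 5 and 6, and 7 by fry. Exposure markers past the threshold were 1, against 0 without the filter, 2 with array weights, Xist, the mean of probe sets or without _x_at and _s_at probe sets, and 3 with the actin ratio. Leaving out 1 array gave 1 to 6 genes higher, 58 to 98 lower, 87 to 162 probe sets and 0 to 2 exposure markers. Gclc reversed to -0.28 with the mean of probe sets and -0.86 without _x_at and _s_at probe sets. Some lists that did not pass turned direction in the test: the alveolar type 2 median was 0.025 as deposited, -0.020 with median centring and -0.16 to 0.26 over single omissions, and the T cell median -0.18 to 0.12 over single omissions. Alveolar type 1 was at 0.11 with array weights and 0.11 without smoke arrays 1 and 2, and endothelial at 0.10 and 0.085. The cause was not tested, although the filter, floor and scaling settings change which genes are tested, and omissions leave fewer arrays.

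With the replicate number as a block over the arrays numbered 1 to 4, 444 genes were higher, 344 lower, 1299 probe sets changed and 2 exposure markers passed; without the block over the same 8 arrays these were 418, 324, 1190 and 2, and Mt1 was -0.035, alveolar type 2 -0.24 and T cell 0.12 in both. The numbers do not pair the arrays: same-numbered deviations correlated at -0.07 to 0.17, and 0 of 4 controls correlated best with their own number. Most of the rise came from leaving out smoke arrays 5 and 6. Dim probe sets have no stated background, which limits what can be said of them.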

Other observations

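Without smoke arrays 1 and 2, a setting chosen after seeing the data, 10 genes were higher after smoke, of which Mid1 (3.92 ± 0.35) and Cyp1b1 (2.03 ± 0.40) were also higher with all arrays. The other 8, named after their values were seen, included the secreted matricellular protein Ccn4 (1.49 ± 0.30, limma adjusted p = 0.0485), the mesenchymal cadherin Cdh11 (0.71 ± 0.14, adjusted p = 0.0485), the carbonic anhydrase Car2 (0.77 ± 0.12, adjusted p = 0.0147) and the signalling adaptor Grb10 (0.79 ± 0.14, adjusted p = 0.0337).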
